A study of Oryza sativa with 8 samples.

How the data were processed

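Rice RNA was profiled by Lasy-Seq in 8 samples: roots and leaves, each from 1 non-transformant (NT) sample and from 1 sample of each of 3 lines overexpressing OsbZIP83. The authors deposited 1 table for all samples, with 1 column per sample matched to it by name. Per the series design text its values are reads per 1000000 (RPM), and they are treated as a normalized signal: in the deposited table each of 3 classes (46120 genes, 10 ribosomal RNAs and 92 ERCC spike-in controls) sums to 1000000 in every library. Per the submitters' processing notes Trimmomatic 0.39, Bowtie 1.2.3 and RSEM 1.2.21 were used with the build IRGSP-1.0; their roles and settings are not given in the sources used here. Gene names and descriptions come from the RAP-DB and Oryzabase columns of the table. Gene start and end coordinates and the separate table of RefSeq names were not used here, and the place of a gene is given by its locus identifier, which holds the chromosome and the order along it.

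The most frequent value above 0 in a library was taken as the value of 1 read, between 0.0280 and 0.0590 RPM. It gave a depth of about 17000000 to 35700000 gene reads. Values were not whole multiples of it: of values below 20 reads, 44.9% to 61.0% lay within 0.1 of a whole number. A test on counts was therefore not run, and limma was used on the log scale. Values of genes totalling 200 to 600 reads, with under 200 in the library, were whole in 9.54% to 12.3% of cases as deposited. After 0.134% to 0.146% of the gene's total over the 8 libraries was added back to each library they were whole in 46.5% to 53.6%, where 20% is the level by chance. This looks like a deduction made before deposit, which no source used here describes; it weighs most on genes abundant in the other tissue. A value of exactly 0 is therefore given as listed at 0, and no fold change within a tissue is given against it in the report. Some differences between tissues rest on such a value, and these genes are named with the results flagged for a closer look.

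Groups were taken from the sample titles. The 3 lines served as replicates and the lone NT sample of a tissue was assumed to vary like them. Analyses used Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 (limma 3.58.1, statmod 1.5.0). The 21991 genes with a mean of at least 1 RPM over the 8 libraries were tested on log2(RPM + 1) with limma (lmFit and eBayes with a trend), with 4 group means and 4 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Contrasts were lines against NT in roots, the same in leaves, and the difference of the 2 effects. Root against leaf was fitted as 4 against 4 samples. Fold changes are on the log2(RPM + 1) scale and understate changes of low genes. SDs are over the 3 lines.

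Genes at least 2-fold from NT in the same direction in all 3 lines, with a mean of at least 5 RPM in the tissue, were also counted without a test, and counted again with each line in turn as the odd sample. In total 33 gene lists, 17 of named genes and 16 by words of the description, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the 66 list tests; of 198 symbols 187 were matched, 24 of them by hand from the annotation text. Estimated correlations and fry were alternatives, and no list call held with an estimated correlation. Named genes were chosen by a rule fixed before the data were examined: the target, the 10 largest increases and decreases per tissue past the threshold with all 3 lines on 1 side, up to 4 members per list past the threshold (filled to 2 with its most abundant members), and the 5 largest in each direction for the other contrasts. Genes whose values are identical to those of another gene, 117 of those tested, are uncertain, since reads may be shared among copies.

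In simulated data 200 of 21991 genes were changed, all drawn from genes with a mean of at least 5 RPM in the tissue. The rates therefore do not cover lower genes. In roots 62.7% of 2-fold, 98.5% of 4-fold and 98.5% of 8-fold changes were recovered, with 14 unchanged genes among 187 called. In leaves 61.2%, 95.5% and 98.5% were recovered, with 11 unchanged among 181. Simulated lists gave 1 call for the list shifted by 0.5 and 0 others. The simulated genes varied independently, whereas the estimated correlation in the data was 0.118 within the histones and 0.516 within the ribosomal proteins. This simulation therefore does not show how the list test fares when the members of a list are correlated.

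Root and leaf samples of a line are paired by the line, per the labels. Deviations of the same line from the group means correlated across 11324 genes at 0.268, -0.0100 and 0.149 for lines 13, 15 and 19, and the estimated correlation within a line was 0.00483. Libraries of a tissue correlated at 0.965 to 0.994 across genes and no pair held identical values, so each counted as 1 sample. The labels give no sequencing batch. Alternatives were the pseudocount, the filter, TMM factors (own code, trimming 30% of log ratios and 5% of mean levels), quantile normalization within a tissue, robust moderation, each line left out, fits on 1 tissue, and the line as a block. The addition of deducted reads, the counts outside chromosome segments and the named differences between tissues under each alternative were added after the data were seen.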

Results

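Gene expression was measured in roots and leaves of hydroponically grown rice of the cultivar Tsukinohikari, supplied with sufficient iron, by Lasy-Seq, a 3′ RNA-seq method in which oligo-dT priming places the reads near the 3′ ends of polyadenylated transcripts. The 8 samples fell into 4 groups. In each of the 2 tissues there was 1 sample of the non-transformant (NT) and 3 samples of plants overexpressing OsbZIP83, a bZIP transcription factor gene, from the lines b83OX-13, b83OX-15 and b83OX-19, called lines 13, 15 and 19 here. The comparison asks which transcripts differ between these lines and NT while iron is sufficient, and whether they differ alike in both tissues. Values were reads per 1000000 (RPM), which summed to 1000000 over the genes of each library. The most frequent value above 0 in a library was taken as 1 read. It put the depth at about 17000000 gene reads in NT roots and 20100000, 31600000 and 24300000 in roots of lines 13, 15 and 19. In leaves the depth was about 22600000 in NT and 35700000, 29400000 and 25000000 in the same lines. Between 27956 and 31186 genes were above 0 in a library, and the 10 most abundant genes held 5.75% to 6.01% of the reads in roots and 13.0% to 14.9% in leaves. The labels do not say whether a sample was 1 plant or a pool, so the p-values measure only the spread between these samples, which were single samples of 3 lines, and NT had no replicate in either tissue.

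OsbZIP83 (locus Os12g0152900, chromosome 12) was higher than in NT in all 3 lines and in both tissues. In roots its level was 32.00 RPM in NT and 154, 186 and 188 RPM in lines 13, 15 and 19, a mean of 176 ± 19.1 RPM (SD, n = 3) and a log2 fold change of 2.42 ± 0.19 (SE, limma adjusted p = 0.000993). In leaves it was 1.62 RPM in NT and 75.3, 100.5 and 94.98 RPM in the lines, a mean of 90.3 ± 13.2 RPM and a log2 fold change of 5.11 ± 0.19 (adjusted p = 2.67e-05). The log2 fold change was smaller in roots than in leaves by a tested difference of -2.70 ± 0.26 (adjusted p = 0.0164), with the NT level being lower in leaves. Without line 19 the root change was 2.37 with an adjusted p of 0.0702, and fits on the 4 samples of a tissue alone gave adjusted p of 0.0519 in roots and 0.0603 in leaves. The difference between the tissues was -2.66 without line 15 and -2.70 without line 19, where it did not pass (adjusted p 0.1196 and 0.241), and -3.26 and -1.55 with pseudocounts of 0.1 and 5 RPM, where it passed.

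**Figure D1:**
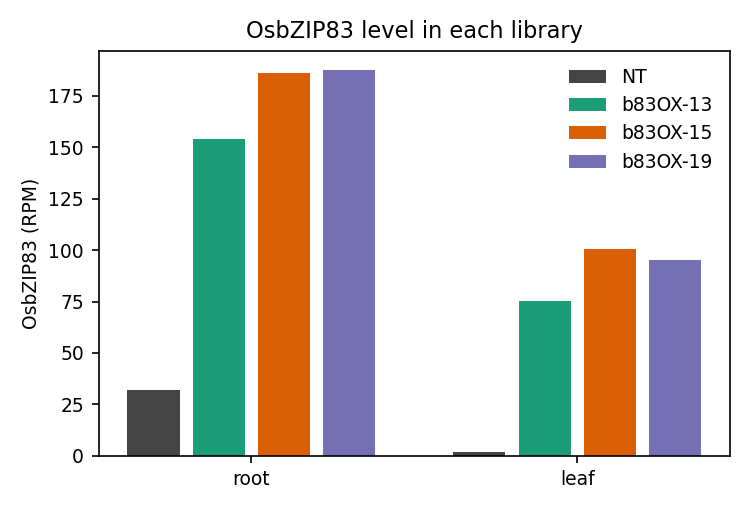
OsbZIP83 level in RPM (vertical axis) in each of the 8 libraries, with 1 bar per library, grouped by tissue and coloured by line. NT stood at 32.0 RPM in roots and 1.62 RPM in leaves, below every overexpression line of the same tissue.

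In roots, the genes that changed most in the lines included several of unknown function. Os07g0511400, annotated as a hypothetical protein, rose from 11.2 RPM in NT to 1283 ± 41.99 RPM (SD, n = 3), a log2 fold change of 6.72 ± 0.16 (SE). Os03g0115800 rose from 1.77 to 215 ± 18.5 RPM, and Os03g0299700, another conserved hypothetical protein, from 1.98 to 128 ± 12.5 RPM. OPR4, similar to 12-oxophytodienoic acid reductase, rose from 1.67 to 118 ± 16.2 RPM. The largest falls included Os10g0137300, similar to BLN1-1, from 961 to 37.6 ± 12.7 RPM.

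Of 21991 genes tested, 256 passed the threshold in roots, 144 higher and 112 lower in the lines (limma, adjusted p 0.05), and 2959 had an unadjusted p under 0.05. Decreases outnumbered increases when no filter was used (179 higher and 505 lower) and with a pseudocount of 5 RPM (154 and 256). Among the other large increases, Os08g0168150 was listed at 0 in NT and at 27.2, 29.5 and 31.8 RPM in lines 13, 15 and 19, and Os10g0315400, similar to a SKIP-interacting protein, was listed at 0 in NT and at 17.9, 18.2 and 17.9 RPM. C3H40, similar to an RNA-binding protein, rose from 3.13 to 76.1 ± 4.28 RPM. Os07g0125000, Os07g0125600 and Os07g0126401, of the allergen V5/Tpx-1 family, had identical values in every library (7.88 RPM in NT, 149.7 ± 21.1 RPM in the lines), so that reads shared among these copies leave the source of the increase of 4.08 uncertain. Among the large decreases, Os11g0596250 fell from 80.5 to 1.76 ± 0.605 RPM, Os09g0339601 from 63.4 to 4.46 ± 0.5602 RPM and Os09g0358000, similar to OsD305, from 29.3 to 1.42 ± 0.377 RPM. Os11g0227800, an NB-ARC domain protein of the kind found in resistance genes, had a log2 fold change of -2.85, and Os11g0234100, Os11g0227600, Os11g0501000 and Os09g0357250 had -3.81, -3.49, -3.36 and -3.22. OsCAB1R, a chlorophyll a/b-binding protein gene at 13298 RPM in NT leaves, was at 190.2 RPM in NT roots, 3.95 RPM in roots of line 15 and listed at 0 in the other lines (adjusted p = 0.00944). Its adjusted p was 0.0550 without line 13 and 0.174 without line 19, and its log2 fold change was -1.91 with estimated deducted reads added back. At least 2-fold from NT in the same direction in all 3 lines were 144 genes of 15332, 93 higher and 51 lower, of which 106 also passed the test. With line 13, 15 or 19 as the odd sample 42, 4 and 8 genes met this rule, and in simulated unchanged roots 34.9 on average and 45 at most. Of the 10 largest increases 1 and of the 10 largest decreases 9 lay in 6 short chromosome segments described with the overlap of the tissues. In the ribosomal RNA class, chloroplast rRNA made up 0.125% of the values in NT roots and 0.450%, 1.43% and 1.86% in roots of lines 13, 15 and 19. Chloroplast rRNA is abundant in leaves and no deducted reads were added back in this class, so this rise may be overstated. Mitochondrial rRNA made up 3.17% in NT roots and 5.58%, 4.96% and 5.78% in the same lines. The count was 91 without line 15, 64 without line 19 and 57 in a fit on the 4 root samples alone. Of the 20 genes with the largest changes, 19, 20 and 18 stayed past the threshold without lines 13, 15 and 19, the losses being OsCAB1R and, without line 19, OPR4 (adjusted p 0.0702). With a pseudocount of 0.1 RPM 15 stayed, the others being the 3 allergen V5/Tpx-1 genes, OsCAB1R and Os11g0227800, and in the fit on roots alone 15.

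**Figure D2:**
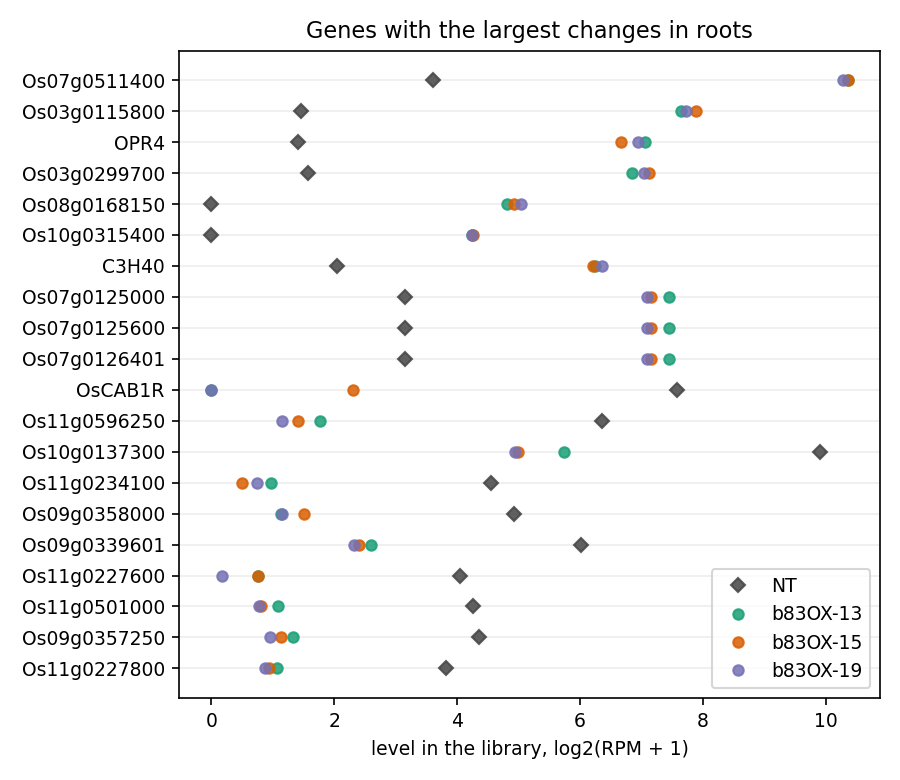
Level of each gene in each root library on the log2(RPM + 1) scale (horizontal axis) for the 10 genes with the largest increases and the 10 with the largest decreases among those past the threshold. Diamonds are NT and circles the 3 lines, which lie on the same side of NT for all 20 genes.

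Genes of iron uptake and mugineic acid synthesis, which acquire iron from the medium, did not pass the test in roots: with limma 0 of 12 did so over all genes, 0 adjusted over the list alone, and 1 at an unadjusted p under 0.05. OsNRAMP5, a manganese, cadmium and iron transporter, was at 225 RPM in NT and 155 ± 23.8 RPM in the lines (adjusted p = 0.252), and OsIRT1, an iron transporter, at 131 and 128 ± 42.9 RPM. Among the 10 iron regulators 0 passed by either adjustment, and 1 had an unadjusted p under 0.05, with IDEF2 at 477 and 489 ± 7.18 RPM and OsbHLH058 at 474 and 437 ± 0.203 RPM. Of 10 genes of internal iron transport and storage, 2 rose. OsNAS3, a nicotianamine synthase, rose from 25.2 to 70.5 ± 6.42 RPM (log2 fold change 1.44 ± 0.22, adjusted p = 0.02705), and OsFER2, a ferritin, from 29.8 to 48.8 ± 0.767 RPM (0.69 ± 0.12, adjusted p = 0.0464). Adjusted over the list alone, 2 were higher and 1 lower. In the phosphate starvation list, OsIPS1, a non-coding transcript induced by phosphate deficiency, fell from 13.9 to 1.49 ± 0.799 RPM (adjusted p = 0.0215), while the phosphate transporter OsPT2 was at 139 and 349 ± 117 RPM (adjusted p = 0.172). That was 1 of 11 members over all genes, and 1 higher and 2 lower adjusted over the list alone. In the circadian clock list of 10, OsFKF1 fell from 36.4 to 14.3 ± 1.22 RPM and OsPRR1 rose from 45.2 to 71.5 ± 4.54 RPM, with 2 higher and 2 lower adjusted over the list alone. OsFKF1 and OsPRR1, like OsCAB1R and GRX9, lay in the 6 chromosome segments. GRX9, 1 of 11 glutaredoxin genes that passed by either adjustment, rose from 39.4 to 108 ± 14.1 RPM. Among 33 germin-like proteins, GLP12-2 and GLP12-4 rose (5 higher and 2 lower adjusted over the list alone). Among 62 class III peroxidases, Os05g0135200 fell from 128 to 65.6 ± 5.91 RPM (1 higher and 1 lower over the list alone). Among 148 cytochrome P450 genes, Os02g0184900 fell from 658 to 363 ± 19.2 RPM, Os02g0185200 from 65.3 to 25.2 ± 4.25 RPM and Os01g0700900 from 4.75 to 2.099 ± 0.228 RPM (1 higher and 3 lower over the list alone). Of these 18 list members past the threshold, OsCAB1R among them, 7, 3 and 1 stayed past it without lines 13, 15 and 19, and the others had adjusted p of 0.0550 to 0.152, 0.0582 to 0.254 and 0.0631 to 0.274. In the fit on roots alone 0 of the 18 stayed (limma), 6 did with a pseudocount of 0.1 RPM, 13 without a filter and 13 with TMM rescaling. Among those lost were OsNAS3 (adjusted p 0.0556), OsFER2 (0.0514) and OsIPS1 (0.267) with that pseudocount and OsFER2 with TMM rescaling (0.0623), a filter at 5 RPM (0.0593) and estimated deducted reads added back (0.137).

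As groups, 6 of the 33 lists passed the test in roots (camera, with a preset correlation of 0.01), 2 higher and 4 lower. The ribosomal proteins were higher (319 genes, median log2 fold change 0.12, adjusted p = 0.000523, and 0.981 as the adjusted p with an estimated correlation), with 2 members past the threshold by either adjustment, Os11g0425800, similar to a 60S protein, and Os03g0452300, of bacterial type. The log2 fold change of the second, 1.10, was 0.39 with estimated deducted reads added back (adjusted p 0.323) and 0.45 with a pseudocount of 5 RPM (0.202). Genes of diterpenoid phytoalexin synthesis were higher (16 genes, 15 of them positive, median 0.68, adjusted p = 0.0137, and 0.882 with an estimated correlation), with 0 members past the threshold by either adjustment and 3 at an unadjusted p under 0.05. OsMAS was at 59.4 RPM in NT and 128 ± 61.9 RPM in the lines, and the list's median was 1.38 in line 13, 0.58 in line 15 and 0.15 in line 19. Without line 13 its adjusted p was 0.0820. The expansins, which loosen cell walls, were lower (31 genes, 25 negative, adjusted p = 0.0137, and 0.882 with an estimated correlation), with 0 members past the threshold over all genes, 1 lower adjusted over the list alone and 6 at an unadjusted p under 0.05. EXPB6 was at 190.1 and 130.4 ± 16.3 RPM. The aquaporins were lower (6 genes, adjusted p = 0.0326, and 0.882 with an estimated correlation), with 0 members past the threshold, 1 lower adjusted over the list alone and 4 at an unadjusted p under 0.05. PIP1A was at 1149 and 892 ± 54.2 RPM, and without line 15 the list's adjusted p was 0.0568. The dirigent and laccase proteins were lower (17 genes, adjusted p = 0.0434, and 0.882 with an estimated correlation), with Os10g0335000, a dirigent protein gene of lignin synthesis, falling from 134 to 43.9 ± 4.73 RPM as the 1 member past the threshold by either adjustment. Without line 19 the list's adjusted p was 0.115. The low oxygen list was lower (7 genes, adjusted p = 0.0442, and 0.882 with an estimated correlation), with OsHB2, a non-symbiotic haemoglobin, falling from 725 to 385 ± 25.9 RPM and OsPDC1, a pyruvate decarboxylase of fermentation, from 4.22 to 1.67 ± 0.238 RPM by either adjustment. Neither passed with a pseudocount of 0.1 RPM (adjusted p 0.504 and 0.166 for OsHB2 and OsPDC1). The list's adjusted p was 0.122 without line 15, 0.0928 without line 19 and 0.0510 with estimated deducted reads added back. The other 27 lists had adjusted p of 0.0745 to 0.982 in roots. They were iron uptake and mugineic acid synthesis, iron regulators, internal iron transport and storage, the methionine cycle, defence, jasmonate, TGA factors and glutaredoxin partners, phosphate starvation, zinc, copper and cadmium transport, the circadian clock, drought and abscisic acid, senescence, root markers, leaf markers, the cell cycle, glutaredoxins, heat shock proteins, peroxidases, glutathione S-transferases, light-harvesting proteins, histones, WRKY factors, chitinases, germin-like proteins, cytochrome P450 enzymes, terpene synthases and metallothioneins.

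In leaves, several of the genes with the largest increases in roots were again far above NT. Os07g0511400 was listed at 0 in NT leaves and at 81.8, 90.7 and 111 RPM in lines 13, 15 and 19. Os03g0299700 rose from 0.465 to 49.8 ± 2.34 RPM (SD, n = 3), Os03g0115800 from 0.327 to 43.2 ± 1.86 RPM and Os08g0168150 from 0.127 to 27.4 ± 1.395 RPM. Os02g0615800, a protein kinase gene, rose from 8.53 to 332 ± 63.9 RPM, a log2 fold change of 5.11 ± 0.61 (SE). Lower in the lines were Os09g0354900, from 34.8 to 0.345 ± 0.0275 RPM, Os09g0355400, a protein kinase gene, from 34.6 to 1.25 ± 0.1200 RPM, and XA39, an NB-ARC resistance gene, from 24.8 to 1.11 ± 0.3897 RPM.

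In leaves 834 genes passed the threshold, 585 higher and 249 lower in the lines (limma, adjusted p 0.05), and 4615 had an unadjusted p under 0.05. With trimmed-mean (TMM) rescaling the split was 463 higher and 360 lower, and with quantile normalization 379 higher and 316 lower. Without a filter it was 336 higher and 356 lower. The other large increases were Os01g0672600, a non-coding transcript (4.45), Os06g0559600 (4.44), Os06g0271500 (4.41) and Os03g0405200, also non-coding, from 0.3405 to 24.8 ± 0.411 RPM. Further decreases were Os11g0596250 (-4.73), Os09g0339601 (-4.03), Os09g0358000 (-4.03), UGT99B3, a UDP-glycosyltransferase gene (-3.75), Os06g0291100 (-3.61), Os09g0357300 (-3.32) and Os11g0234100 (-3.22). At least 2-fold from NT in all 3 lines were 327 genes of 13515, 245 higher and 82 lower, of which 248 also passed the test. With line 13, 15 or 19 as the odd sample 29, 114 and 38 genes met this rule, and in simulated unchanged leaves 26.7 on average and 37 at most. The simulated genes varied independently, and the count for line 15 lay far above theirs. The simulated level may therefore understate what 1 odd sample gives. Of the 10 largest increases 1 and of the 10 largest decreases 9 lay in the chromosome segments. The count was 211 without line 15, 90 without line 19 and 16 in a fit on the 4 leaf samples alone. Of the 20 genes with the largest changes, 20, 19 and 17 stayed past the threshold without lines 13, 15 and 19. Those lost were Os06g0559600 (adjusted p 0.0558 without line 15) and, without line 19, Os02g0615800, Os01g0672600 and Os06g0559600, at 0.0581 to 0.0911. With a pseudocount of 0.1 RPM 19 stayed, without Os02g0615800, and in the fit on leaves alone 8.

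**Figure D3:**
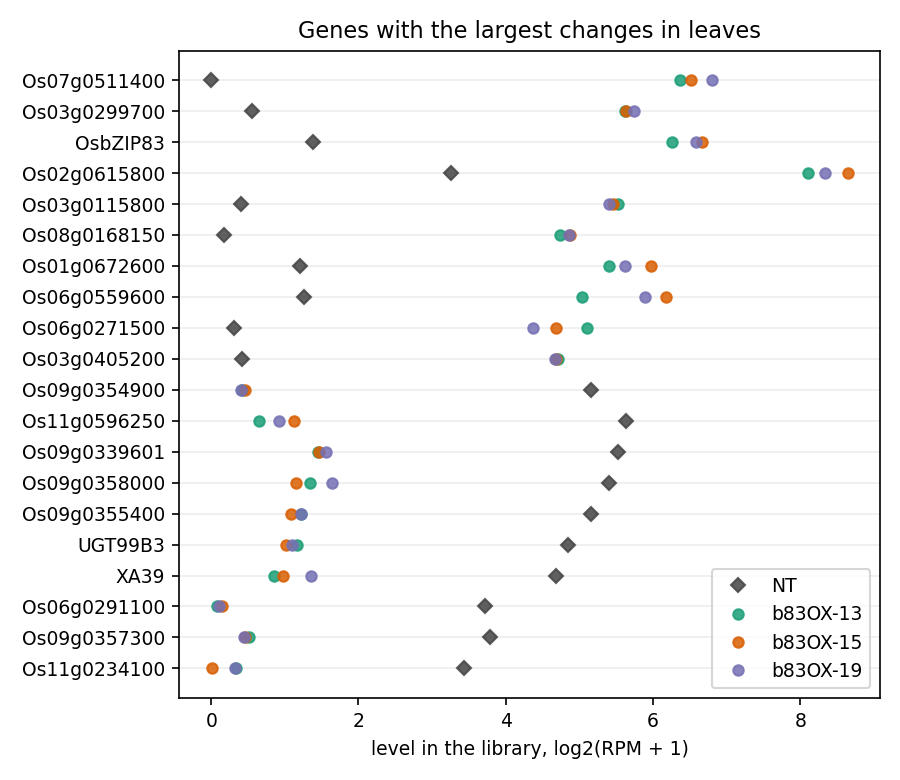
Level of each gene in each leaf library on the log2(RPM + 1) scale (horizontal axis) for the 10 genes with the largest increases and the 10 with the largest decreases among those past the threshold. Diamonds are NT and circles the 3 lines, which lie on the same side of NT for all 20 genes.

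In the iron lists, OsNAS3 fell in leaves, from 21.8 to 5.53 ± 1.35 RPM (log2 fold change -1.82 ± 0.22, adjusted p = 0.00739). It was the 1 of 10 genes of internal iron transport and storage to pass over all genes, with 1 higher and 1 lower adjusted over the list alone. The ferritin OsFER1 was at 1060.0 and 1535 ± 183 RPM (adjusted p = 0.136). Of iron uptake and mugineic acid synthesis genes 0 of 12 passed, and of iron regulators 0 of 10, by either adjustment (limma). At an unadjusted p under 0.05 there were 1 and 2. OsNAS1, OsNAS2, TOM1, OsYSL15, OsIRT2 and the regulator OsIRO2 were listed at 0 in all leaf libraries and could not pass. OsIRT1 and OsNRAMP5 were at most 0.424 and 0.0118 RPM in leaves. The counts therefore say nothing about a response of these genes in leaves. The mugineic acid synthase OsDMAS1 was at 17.1 and 20.7 ± 3.08 RPM and OsbHLH060 at 118 and 119.9 ± 5.94 RPM. OsARD1, an acireductone dioxygenase of the methionine cycle, rose from 2.56 to 31.4 ± 14.7 RPM, 1 of 12 members (1 higher and 1 lower adjusted over the list alone). CYP71Z6, a cytochrome P450 of phytoalexin synthesis, rose from 7.603 to 24.1 ± 1.05 RPM, 1 of 16 by either adjustment. OsJAZ11, a jasmonate signalling repressor, rose from 16.4 to 48.2 ± 11.2 RPM, 1 of 13 (2 higher and 1 lower over the list alone). OsPT8, a phosphate transporter, rose from 25.2 to 63.8 ± 15.01 RPM, 1 of 11 by either adjustment, and OsHMA5, a copper transporter, fell from 2.08 to 0.786 ± 0.159 RPM, 1 of 13 (1 higher and 1 lower over the list alone). Of 10 clock genes OsLUX rose from 289.8 to 634 ± 49.7 RPM, OsPRR1 rose from 66.01 to 109.6 ± 1.53 RPM and OsFKF1 fell from 84.2 to 36.9 ± 1.91 RPM, the same numbers adjusted over the list alone. OsPRR1, OsFKF1 and GRX9 lay in the chromosome segments. OsADH1, an alcohol dehydrogenase, rose from 11.9 to 34.7 ± 8.62 RPM (1 of 7), and OsSalT fell from 50.4 to 22.1 ± 2.48 RPM (1 of 6 drought and abscisic acid genes), each by either adjustment. Among 63 WRKY factors, WRKY8 rose from 7.93 to 31.4 ± 4.64 RPM and WRKY1 rose, while WRKY25 and WRKY68 fell. In all 3 were higher and 2 lower, and 4 and 2 adjusted over the list alone. Of 29 chitinase genes, Os01g0860500 rose from 8.27 to 32.7 ± 5.23 RPM and DIP3, a xylanase inhibitor of the chitinase family, fell from 258 to 102 ± 8.85 RPM (4 higher and 1 lower over the list alone). GRX9 rose from 30.4 to 77.6 ± 1.03 RPM, and PAO4, a polyamine oxidase placed among the germin-like proteins by the words of its description, from 24.5 to 67.5 ± 3.09 RPM. Of the 40 list members past the threshold, 26, 9 and 3 stayed past it without lines 13, 15 and 19, and the others had adjusted p of 0.0504 to 0.113, 0.0514 to 0.171 and 0.0555 to 0.206. In the fit on leaves alone 0 of the 40 stayed (limma), 18 did without a filter, 34 with a pseudocount of 0.1 RPM, 34 with 5 RPM and 36 with TMM rescaling.

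As groups, 3 of the 33 lists passed the test in leaves, all lower in the lines. The histones, which package DNA, were lower (49 genes, 40 of them negative, median log2 fold change -0.22, camera adjusted p = 2.20e-10, and 0.882 as the adjusted p with an estimated correlation). Of them 8 fell over all genes and 11 adjusted over the list alone. Linker histone H1 genes were among them: Os04g0253000 fell from 552 to 242 ± 9.399 RPM and Os03g0799000 from 226 to 100.1 ± 8.57 RPM, as did Os07g0184800, an H1 variant, from 135 to 75.2 ± 8.66 RPM, and Os07g0549900, similar to histone H4. The light-harvesting and photosystem proteins were lower (45 genes, 39 negative, median -0.22, adjusted p = 1.30e-07, and 0.882 with an estimated correlation). Os03g0333400, a photosystem II protein gene, fell from 850.2 to 536 ± 55.5 RPM as the 1 member past the threshold over all genes, with 0 adjusted over the list alone. The leaf tissue markers were lower (10 genes, median -0.15, adjusted p = 0.0137, and 0.882 with an estimated correlation). This list overlaps the light-harvesting list, with OsCAB1R in both, so these calls are not independent. OsRCA, Rubisco activase, fell from 2198 to 1323 ± 149.6 RPM, 1 of 10 over all genes and 2 adjusted over the list alone, while the Rubisco small subunit OsRBCS3 was at 27382 and 27014 ± 453 RPM. The list's adjusted p was 0.107 without line 19 and 0.0531 with estimated deducted reads added back. Among lists that did not pass (adjusted p 0.115 to 0.982), heat shock proteins had 3 higher and 3 lower of 98 (4 and 4 adjusted over the list alone), among them HSP16.9A higher and HSP17.9B lower. Class III peroxidases had 2 higher and 1 lower of 62 by either adjustment, and cytochrome P450 enzymes 4 higher and 1 lower of 148 (3 and 0 over the list alone). TCHQD1, a glutathione S-transferase, and EXPB3, a beta-expansin, were the members of their lists past the threshold, the first higher and the second lower, and Os11g0516100 and Os07g0680900 passed among the ribosomal proteins, in opposite directions and not over the list alone. The lists of defence genes, TGA factors and glutaredoxin partners, senescence, root markers, cell cycle, dirigent and laccase proteins, aquaporins, terpene synthases and metallothioneins had 0 members past the threshold in leaves (limma). The second of these was tested without OsGRX9, a symbol given to several loci, while GRX9 (Os02g0618100) was counted among the glutaredoxins. Adjusted over the list alone 3 senescence genes were higher and 3 aquaporins lower, and 2, 1, 3, 0, 0, 2, 3, 1 and 3 members of these 9 lists had an unadjusted p under 0.05. Among the 8 root markers tested, 1 had a positive and 1 a negative log2 fold change in leaves. The other root markers had a log2 fold change of 0 there and could not pass. The direction of the test, the median and the mean shared no common sign in 4 lists in roots and 18 in leaves, none of them a list that passed.

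Many genes changed in both tissues in the same direction. The set held Os07g0511400, Os03g0115800, Os03g0299700, GRX9, OsPRR1 and OsbZIP83 as higher and Os11g0596250, Os09g0358000, Os09g0339601, OsFKF1 and XA39 as lower. Of the genes past the threshold, 63 were higher in both tissues, where 3.83 would fall together in independent lists of these sizes, and 38 were lower in both, against 1.27. The tests of both tissues share 1 estimate of the spread per gene, so the lists are not independent and these levels may be too low. There was 1 gene higher in roots and lower in leaves, which was OsNAS3, and 1 the other way, HSD1 (Os11g0499600), named here after its values were seen. The tissues had separate NT libraries, each without a replicate. With a line in place of NT as the odd sample in both tissues, at most 3 genes passed in both in the same direction, against 101 with NT. With a line as the odd sample NT counts among the replicates, so any difference between NT and the lines adds to the spread and lowers the count. It is therefore not a level by chance for the 101. These 101 genes were unevenly placed along the chromosomes, ordered by locus number. Chromosome 11 held 39 of them, and 56 lay in 6 segments with 438 tested genes. A segment was a run of at least 4 of these genes, each at most 50 tested genes from the next, so the segments were drawn from the genes they hold. Random placements of 101 genes gave 0.652 such segments on average and 4 at most. The segments ran from Os02g0614500 to Os02g0618200, Os06g0170500 to Os06g0177300, Os09g0325300 to Os09g0358000, Os10g0137100 to Os10g0178500, Os11g0225300 to Os11g0241700 and Os11g0515500 to Os11g0605100. All 4 and 7 both-tissue genes of the segments on chromosomes 2 and 6 were higher in the lines, including C3H40, whereas 8 of 9 in the segment on chromosome 9 and 19 of 22 in the longer segment on chromosome 11, including XA39, were lower. Directions were mixed in the other 2, with 3 higher and 1 lower on chromosome 10 and 5 higher and 5 lower in the shorter segment on chromosome 11. Outside the segments 175 genes passed in roots and 751 in leaves.

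**Figure D4:**
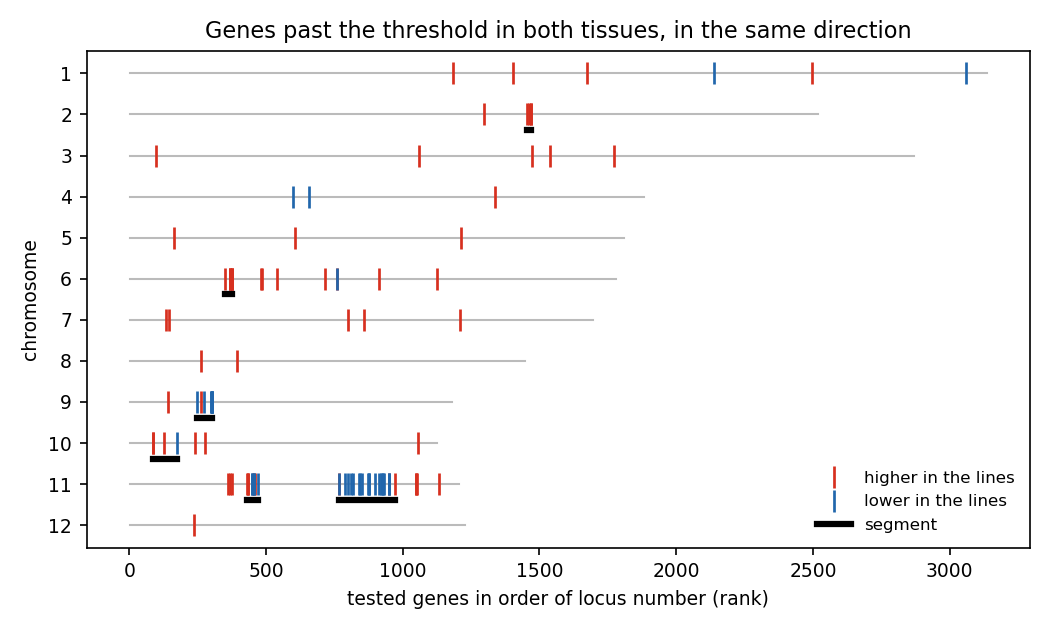
Position of the 101 genes past the threshold in both tissues in the same direction, by rank of the tested genes in order of locus number (horizontal axis) on each chromosome (vertical axis), red for higher and blue for lower in the lines. Black bars mark the 6 segments, which held 56 of the genes.

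The effect of the lines differed between the tissues for a smaller set of genes, which included a gene of iron chelator synthesis. OsNAS3 rose in roots and fell in leaves, a tested difference of 3.27 ± 0.30 (SE) on the log2 scale (limma adjusted p = 0.0139). STV11, a sulfotransferase gene of resistance to stripe virus, was at 7.11 RPM in NT roots and 15.96 ± 3.68 RPM in the lines, and at 17.3 RPM in NT leaves and 1.22 ± 0.501 RPM in the lines (difference 4.11 ± 0.42, adjusted p = 0.0178). Os09g0355400 was at 0.411 and 0.259 ± 0.0766 RPM in roots against the fall in leaves given above (difference 3.82). Os10g0137300 fell in roots and was listed at 0 in all 4 leaf libraries, and Os11g0501000, which fell in roots, was at 0.0214 RPM in NT leaves and listed at 0 in leaves of the lines. Os02g0621300, a fatty acid hydroxylase domain gene, rose in leaves from 0.317 to 16.97 ± 4.18 RPM and was listed at 0 in NT roots. Os01g0162300, a leucine-rich repeat gene, and its neighbour Os01g0162400 were at 29.4 ± 11.9 and 33.2 ± 13.1 RPM in leaves of the lines against 1.56 and 1.89 RPM in NT leaves. Os10g0137300, Os11g0501000, Os02g0621300, Os01g0162300 and Os01g0162400 were listed at 0 in NT or in all lines of 1 tissue. Their differences rest almost wholly on the other tissue and are not measured differences between tissues. In all 84 genes passed, 27 with a more positive effect in roots and 57 with a more positive effect in leaves, and 3338 had an unadjusted p under 0.05. The split was 25 and 32 with TMM rescaling and 26 and 29 with quantile normalization, and it turned to 16 and 9 without line 13 and to 15 and 11 with the line as a block. The count was 25 without line 13, 1 without line 15 and 0 without line 19, and 26 with the line as a block, 21 of them among the 84. Of the 22 named genes that passed, OsNAS3 and OsbZIP83 among them, 13 stayed past the threshold with the line as a block, 9 with a pseudocount of 0.1 RPM, 15 with TMM rescaling, 14 with quantile normalization, 7 without line 13 and 0 without line 15 or line 19. OsNAS3 had adjusted p of 0.0605, 0.0607 and 0.241 without lines 13, 15 and 19.

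Root and leaf libraries differed as their labels say. MTI4C, a metallothionein gene, was at 12858 to 13547 RPM in the 4 root libraries and listed at 0 in the 4 leaf libraries, and Os01g0284500, similar to a nectarin, was at 3343 to 3662 RPM in roots and listed at 0 in leaves. OsRBCS3 and OsRBCS2, Rubisco small subunit genes, plastocyanin (PC) and Os01g0303000, similar to the Calvin cycle regulator CP12, were listed at 0 in all root libraries and at 27382, 26563, 8255 and 11763 RPM in NT leaves. MTI3A, another metallothionein gene, was listed at 0 in roots and at 24494 RPM in NT leaves. Os02g0583700, Os02g0582900 and Os09g0409100, conserved hypothetical proteins, were at 9836, 3906 and 3785 RPM in NT roots and listed at 0 in leaves. Genes abundant in a tissue were often at exactly 0 in the other: 59.8% of genes with a leaf mean of at least 1000 RPM were at 0 in all root libraries, against 0.775% of those between 10 and 100 RPM, so a listed 0 is not read as absence. Between root and leaf 18184 genes passed, 12856 higher in roots and 5328 higher in leaves (limma, 4 against 4 samples), over a median log2 difference of 0.59. With TMM rescaling, which brought that median to 0.07, the split was 9298 and 8243.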

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

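The comparison of ribosomal RNA values was chosen after the data were seen; the tests of the difference between tissues were planned. The overexpression effect, in limma's test of its difference between roots and leaves, differed for 84 genes. That count was 25 without line 13, 1 without line 15 and 0 without line 19. Values here are the log2 effect in roots minus that in leaves. For the target OsbZIP83 it was -2.70, where NT leaves had the lowest level. OsNAS3, higher in roots and lower in leaves of the lines, stood at 3.27. The largest values were 4.11 for STV11, 3.99 for Os07g0125000, Os07g0125600 and Os07g0126401, whose values are identical, and 3.82 for Os09g0355400. At the other end were Os10g0137300 at -4.69, Os02g0621300 at -3.74, Os01g0162300 and Os01g0162400, both at -3.46, and Os11g0501000 at -3.33. These 5 genes, Os10g0335000 and CYP71Z6 were listed at 0 in NT or in all 3 lines of 1 tissue, so that their values rest almost wholly on the other tissue and are not measured differences between tissues. Among genes that fell in roots, Os11g0227800 had -2.56, Os11g0227600 -2.46 and the dirigent gene Os10g0335000 -1.60. Among genes that rose in leaves, WRKY8 had -2.30, the chitinase gene Os01g0860500 -1.83 and CYP71Z6 -1.50. Among genes that fell in leaves, Os09g0354900 had 3.19, UGT99B3 1.49 and the histone H1 gene Os03g0799000 1.38. With a pseudocount of 0.1 RPM UGT99B3 turned to -0.60 (adjusted p 0.627), so its sign depends on the pseudocount. Os03g0115800, higher in both tissues, had 1.23, which was 0.18 with a pseudocount of 0.1 RPM (adjusted p 0.674) and 1.84 with 5 RPM. Os09g0354900 was 2.08 with 0.1 RPM (adjusted p 0.113). With that pseudocount Os07g0125000, Os07g0125600 and Os07g0126401 were at 4.07 (adjusted p 0.185), Os11g0227800 at -2.47 (0.286) and Os11g0227600 at -1.88 (0.433). In all 13 of the 22 named genes did not pass with it and 9 did. With 5 RPM values more than 1.5 times smaller that still passed were -1.55 for OsbZIP83, 2.62 for STV11, -2.03 for Os02g0621300, -1.97 for Os11g0501000, -1.62 for Os11g0227600 and -1.53 for Os11g0227800.

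In the ribosomal RNA class, which no comparison used, 6 transcripts were higher in roots of every line than in NT roots, and 3 of them met the rule of more than 2-fold at a root mean of at least 100 RPM. The lowest line over NT was 2.30-fold for chloroplast 16S rRNA, 4.63-fold for chloroplast 23S rRNA and 2.32-fold for nuclear 5S rRNA, differences that were not tested. Chloroplast 23S rRNA stood at 704 RPM of its class in NT roots and at 3262, 12519 and 16551 RPM in roots of lines 13, 15 and 19, against 675210 to 705379 RPM in leaves. A deduction like that inferred from gene values would weigh most on such transcripts, which are abundant in the other tissue. It was neither estimated nor added back in this class, so the chloroplast folds in roots may be overstated. The other 3 were mitochondrial: 26S rRNA stood at 28909 RPM in NT roots and 50878, 44580 and 52421 RPM in the lines, 18S rRNA at 2778 and 4848, 4940 and 5253 RPM, and 5S rRNA at 17.4 and 74.3, 39.0 and 98.0 RPM. In the 14 groups of 4 samples examined, 0 had a sample set apart from the others by Dixon's criterion, where chance gives about 1 in 20.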

How the results depend on the processing

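The addition of estimated deducted reads and the counts outside chromosome segments were chosen after the results were seen. A count test on whole reads was planned and not run, since whole reads could not be recovered. Of the summary results under all alternatives, 76 stayed within 1.5 times the reported value or on the same side of the threshold, 34 counts moved further and 3 tests lost significance. Counts of root genes (256) were 410 with a pseudocount of 5 RPM, 684 without a filter, where decreases were in the majority with both, 121 with a filter at 5 RPM, 57 on the root samples alone and 64 to 253 without 1 line. Counts of leaf genes (834) were 16 on the leaf samples alone and 90 to 803 without 1 line. Counts for the difference between tissues (84) were 161 with a pseudocount of 5 RPM, 245 without a filter, 31 with a filter at 5 RPM, 55 with quantile normalization, 135 with robust moderation, 0 to 25 without 1 line, and 26 with the line as a replicate block, 21 of them among the 84. With it 9 of 22 named genes lost the call of a difference, as did 13 with a pseudocount of 0.1 RPM, 8 with quantile normalization, 7 with TMM factors and 7 of 16 with a filter at 5 RPM. The block changed no other count past 1.5 times. Fewer samples or fewer genes enter the fits on 1 tissue, without a line and with a higher filter; for the others the cause was not tested. Root against leaf kept its count within 13479 to 22305, 18273 with the line as a paired block.

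The OsbZIP83 change in roots, 2.37 to 2.51 without 1 line, lost significance without line 19 and on the root samples alone (2.42, adjusted p 0.0519), and in leaves, 5.03 to 5.24, on the leaf samples alone (5.11, adjusted p 0.0603); over all its alternatives the adjusted p ran up to 0.0702 in roots and 0.0603 in leaves. Genes 2-fold from NT in all lines (144 in roots, 327 in leaves) numbered 498 and 908 at 1.5-fold, 65 and 110 at 3-fold, 274 and 491 with a mean of at least 1 RPM, 68 and 155 with at least 20 RPM, and 164 to 245 and 382 to 520 without 1 line, where fewer lines have to meet the rule. Lists past the threshold (6 and 3) were 0 and 0 with estimated correlations, 0 and 0 with fry, which tests a set's own genes (4 and 2 lists at an unadjusted p under 0.05), 5 to 6 and 3 to 5 without 1 line, and 6 in leaves with reads added back. Of 2575 values of named genes and lists under alternatives, 2201 stayed the same, 355 lost significance, 2 gained it, 17 moved otherwise and 0 that had passed turned direction, which leaves out differences between tissues of genes named for another comparison, where UGT99B3 turned from 1.49 to -0.60 with a pseudocount of 0.1 RPM; of 204 named values 31, 59 and 71 lost it without lines 13, 15 and 19, and of 195 named values 28 with a pseudocount of 0.1 RPM and 29 without a filter, and 73 of 175 on the samples of 1 tissue alone. The median log2 difference between root and leaf went from 0.59 to 0.07 with TMM factors, and that of the effect's difference from -0.10 to 0.03. With 3 lines and 1 NT sample, 62.7% of simulated 2-fold changes were recovered in roots, among genes with a mean of at least 5 RPM there.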

Other observations

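The placement of genes along the chromosomes was noticed and tested after the results were seen, as were the interval around the correlation in the segments and the values of line 15 below, and the addition of deducted reads was chosen after the data were seen; the other tests here were set out beforehand. Leaves of line 15 stood apart in defence genes, which were 0 of 15 past the threshold in leaves (limma, over all genes and adjusted over the list alone). RSOsPR10, a pathogenesis-related gene, was at 0.664 RPM in NT leaves, 2.93 and 7.20 RPM in leaves of lines 13 and 19 and 103 RPM in line 15. OsWRKY76, a WRKY factor of defence, was at 5.02, 22.0, 29.6 and 98.8 RPM in the same order, and OsPBZ1, another pathogenesis-related gene, at 61.1, 70.5, 53.6 and 196.9 RPM. OsPR1b was at 2.25, 12.4, 4.25 and 43.1 RPM, and the chitinase gene OsCht1 at 3.22, 7.75, 9.35 and 44.5 RPM. The list's median log2 fold change was 0.30 in line 13, 2.55 in line 15 and 0.41 in line 19. In roots RSOsPR10 was at 117 RPM in NT and 407, 250.3 and 191 RPM in lines 13, 15 and 19. With line 15 as the odd leaf sample 114 genes met the rule of a 2-fold difference from all other leaf samples, 109 of them higher in line 15.

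Genes past the threshold in both tissues lay close together: 65.3% of the 101 had another within 25 tested genes, against at most 45.5% in 10000 random placements, which argues against chance placement. This closeness was not particular to them. Of 153 genes past the threshold in roots only, 52.3% had another of their set as near, against at most 43.1% in random placements. Of 731 genes past it in leaves only, the share was 81.4%, against 81.5% on average in random placements. With 1 gene kept per description on a chromosome and none of identical values, the share for both tissues was 60.9% of 92 genes, against at most 41.3%. Genes described as hypothetical or non-protein-coding, or without a description, were all kept unless their values were identical to another's. The result argues against reads shared between neighbouring copies of the same description or of identical values. It does not cover other copies. A genetic difference between NT and the lines in the 6 segments may contribute: root and leaf log2 fold changes of 145 segment genes past the threshold in neither tissue correlated at r = 0.401 across genes, which are not independent replicates. That lay below the bound set beforehand (0.501, the 95th percentile of 1000 random segment sets), but its bootstrap interval, added after the value was seen, was 0.227 to 0.563 and spans the bound, so the test neither excludes nor backs a genetic difference. The biological alternative, the overexpressed factor acting on neighbouring genes, was not testable because each line carries the transgene and NT does not, so the 45 genes outside the segments bound nothing and these explanations cannot be told apart.

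Of the genes past the threshold in leaves, 70.1% were higher in the lines, and library scaling could account for part of this. With TMM factors the share was 56.3%, between the bounds of 55% and 60% set beforehand, and with quantile normalization 54.5%, so scaling stays open. Without a filter it was 48.6% (336 higher and 356 lower), so the excess of increases depends on which genes are tested. With estimated deducted reads added back it was 68.0%, which argues against the deduction, and without 1 line it was at least 64.4%, which argues against a single library of the lines. All these shares rest on the lone NT leaf library, which was the shallowest leaf library (about 22600000 gene reads) and had the fewest genes above 0 (27956). A difference of that library and an effect of the overexpression itself stay open beside scaling, as untested.

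Histone and light-harvesting genes were lower in leaves of the lines, with medians of -0.22 and -0.22. Both medians lay at percentile 0 of 10000 lists matched on leaf level (central 95% from -0.01 to 0.17 and from -0.02 to 0.02). For the histones this argues against a general fall of genes at their level. Matched genes were drawn from nearby ranks of leaf level, and draws past the top were set to the most abundant gene. Light-harvesting genes are abundant in leaves, so such draws can repeat 1 gene and narrow the range. No conclusion is drawn from it for them. The highest of the 6 medians per line was -0.155, which argues against a single library of the lines. A chance difference of the lone NT leaf library could also give this: of the 4 choices of odd leaf sample 1, NT, gave a histone median as far from 0, the highest other being 0.0911 in size, and 4 choices are too few to exclude chance. An effect of overexpression stays open as the biological explanation.

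For root against leaf, 1 of the 35 splits of the 8 samples into 4 and 4, the real one, gave 18184 genes, and the highest other gave 9. Each other split mixed roots with leaves in its groups, so the tissue difference entered the spread of its test. The counts of the other splits are thus no level by chance for 18184. Samples are paired by line, and 8 splits part all 4 root and leaf pairs, too few for a share under 0.05. Among these 8 the highest other gave 0 genes (limma), and over all other splits at most 829 genes had an unadjusted p under 0.05. The real split ranked first, and no conclusion about chance is drawn from the splits.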
